A study of Mus musculus with 2 samples.

How the data were processed

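Single-cell 3' RNA libraries of the 10x Chromium platform were prepared from enzymatically digested skin wounds, per the labels' protocols, with cells pooled from 2 mice in each of the 2 groups and taken on day 6 after injury. Group membership came from the disease state given in the labels. The deposited matrices hold raw UMI counts per gene and barcode, per the file headers made with Cell Ranger software version 3.0.2. The genome build was mm10, per the submitters' processing notes. The annotation release was not given in the sources used here. The diabetic model was not named in the labels, which speak of mice of each strain. Both matrices list the same 31053 genes, of which 71 entries share a symbol with another entry. Such entries, Aldoa among them, were kept apart by identifier and were not matched to lists or named.

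Cells with at least 500 genes and under 10% mitochondrial UMIs passed the filter, leaving 1123 non-diabetic and 1755 diabetic cells. Scrublet, run per library through scanpy version 1.11.5, marked 3 and 5 cells as doublets, which were removed. These are low shares, 0.267% and 0.285%, so doublets may remain. Counts were scaled to the same total per cell and log-transformed. The 2000 most variable genes, chosen within each library, gave 30 principal components, and a graph of 15 neighbours was clustered jointly with leidenalg version 0.10.2 at resolution 1. No batch correction was made.

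Clusters were named from 18 marker sets chosen before the data were examined. A name required at least 3 markers, and at least 50% of the set, at 2-fold or more over other cells and in at least 10% of the cluster's cells. This scoring rule was set after the data were seen. A cluster stayed unnamed where another class had more markers among its top 10 genes. Clusters of low depth, or with stromal markers at 5 times or more the level of other cells, were set aside. The monocyte/macrophage set comprised the monocyte-like, macrophage-like and unnamed clusters, with 944 non-diabetic and 1618 diabetic cells.

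Counts were summed per library over these cells and divided by the library sum to give CPM. The log2 ratio used sums with 0.5 added, and a gene counted as measured with at least 20 UMIs over both libraries. Intervals are Clopper-Pearson for shares, exact Poisson for sums, conditional exact binomial for ratios and from 500 Poisson draws for list medians. A fold against a count of 0 used a floor of 3 counts in that sum. Each list median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. With 1 library per group no test across cells or genes was made.

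Named genes followed a rule written before the data were examined: the 12 highest and 12 lowest log2 ratios among genes at 100 CPM or more in a library, leaving out mitochondrial, ribosomal protein, haemoglobin, sex-linked and unnamed gene models. Up to 4 members of each of the 18 lists but the sex-linked one, at 20 CPM or more, were added. The 5 highest and 5 lowest within each class, and a set of always-named genes, completed it. The text names part of the list members. Near-identical copies were sought by aligning the transcripts of the highest and lowest genes to GENCODE M21 transcripts with BLAST version 2.17.0, at 95% identity over at least 200 bases. Coordinates come from GENCODE M21 on the same build, where 11699 of the 11711 measured identifiers were found.

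Cycling was called at 2 or more UMIs of the G2/M list after thinning each cell to 2000 UMIs. Calculations used Python 3.11.15 and, for alternative scalings, edgeR version 4.0.16 and DESeq2 version 1.42.0 in R 4.3.3. The ratio intervals were tested on simulated Poisson sums for the diabetic over non-diabetic comparison, with 200 genes changed. The intervals assume such sums, so this checks the calculation only. It says nothing on clustering, naming or variation between cells or mice. Intervals held the true ratio for 96.0% of 11530 unchanged genes, and for 92.9% of 70 genes changed 1.5-fold, 89.4% of 66 changed 2-fold and 96.7% of 61 changed 4-fold. Alternatives covered cell filters, doublets, the choice of clusters, clustering resolution, centring, depth, scaling, count filters and the cycling rule. The leading genes of 1 monocyte-like cluster and some single genes of the lists are not reported here.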

Results

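Gene expression was measured in single monocytes and macrophages isolated from the skin wounds of mice with and without diabetes, on day 6 after wounding. The series title asks how heterogeneous these wound cells are in the 2 conditions. Each condition was represented by 1 library, made from cells pooled from 2 mice, so no difference below has a replicate check and none was tested. The labels speak of mice of each strain without naming the strains. A strain difference therefore cannot be told apart from diabetes in any comparison below. The non-diabetic library held 2026 barcodes and 17559986 unique molecular identifiers (UMIs), with a median of 5094.5 UMIs per barcode. The diabetic library held 2214 barcodes and 31730014 UMIs, with a median of 14633.5. Mitochondrial transcripts made up at least 10% of the UMIs in 43.9% of the non-diabetic barcodes (95% interval 41.7% to 46.1%) and in 20.2% of the diabetic barcodes (18.5% to 21.9%). After filtering, 1120 non-diabetic and 1750 diabetic cells were kept, with medians of 14064 and 16304.5 UMIs per cell. All intervals are 95% and cover counting error only, not the variation between animals. Those of CPM, ratios and list medians treat each UMI as independent, so they also leave out the variation between cells.

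The first comparison asked which cell types the libraries held. Classical monocyte-like, macrophage-like, conventional dendritic cell-like and neutrophil-like clusters were found. Most of the remaining cells fell in unnamed clusters, kept in the monocyte/macrophage set by exclusion and not by the naming rule. By share of markers, the Stfa3-led cluster matched neutrophils best (3 of 10). The Inhba-led cluster matched Langerhans cells (1 of 4) and the Tppp3-led cluster keratinocytes (1 of 7). A Csf1r UMI was found in 273 of 302 diabetic Stfa3-led and 273 of 333 non-diabetic Inhba-led cells. The other unnamed clusters matched monocyte or macrophage sets best. Cells outside the monocyte/macrophage set made up 15.7% of the non-diabetic cells (176 of 1120, interval 13.6% to 18.0%) and 7.54% of the diabetic cells (132 of 1750, 6.35% to 8.88%). Dendritic cell-like cells, led by Klrd1 and Cd209a, made up 10.7% of the non-diabetic cells (8.96% to 12.7%) and 3.31% of the diabetic cells (2.53% to 4.26%). Neutrophil-like cells, led by Retnlg and G0s2, numbered 1 of 1120 and 17 of 1750. A cluster mixed with stromal cells, also counted outside the set, held 0.804% and 3.03%. The share outside the set was higher in the diabetic library, at 21.4% against 10.2%, when all deposited barcodes were clustered without a filter.

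Among the monocyte/macrophage cells, monocyte-like cells made up 34.9% in the non-diabetic library (329 of 944, interval 31.8% to 38.0%) and 10.6% in the diabetic library (172 of 1618, 9.17% to 12.2%). They fell into 2 clusters, 1 led by the interferon-induced genes Ifit2, Ifit3 and Mx1, with 188 non-diabetic and 37 diabetic cells, and another with 141 and 135 cells. Macrophage-like cells made up 2.33% in the non-diabetic library (22 of 944, 1.47% to 3.51%) and 13.5% in the diabetic library (219 of 1618, 11.9% to 15.3%). They came from a cluster led by the haemoglobin scavenger receptor gene Cd163 and a cluster led by Ccl8 and Gas6. A further cluster, led by Cx3cr1, had 5 of the 12 macrophage markers and stayed unnamed. It held 1.43% of all kept non-diabetic and 16.7% of all kept diabetic cells. Unnamed clusters held 62.8% of the non-diabetic and 75.8% of the diabetic monocyte/macrophage cells. Of the 16 clusters, 10 took over 90% of their cells from 1 library, so a cluster may stand for a library and not for a cell type. The cluster led by Inhba held 333 non-diabetic and 2 diabetic cells. The cluster led by Stfa3, Fst and Lcn2 held 302 diabetic and 0 non-diabetic cells, where the interval of the non-diabetic share reaches 0.329%.

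**Figure D1:**
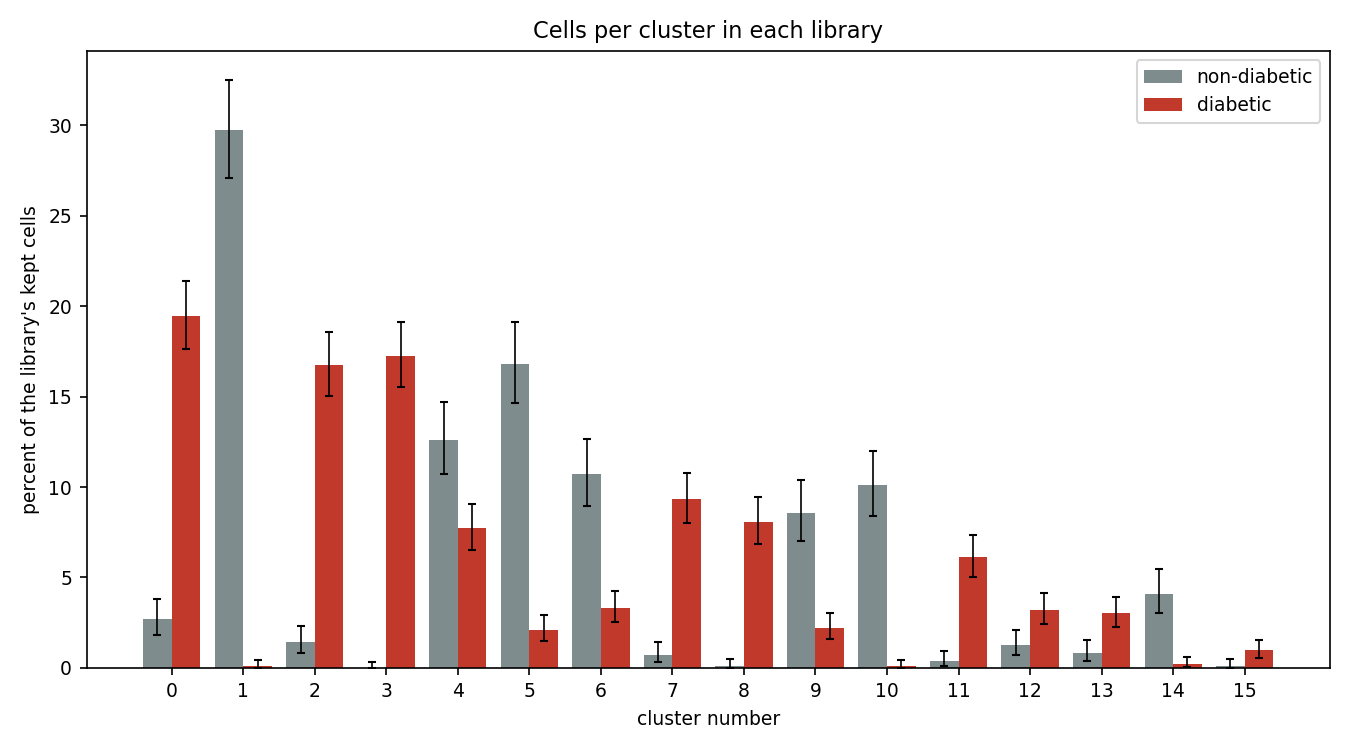
Percent of each library's kept cells in each of the 16 clusters, numbered on the x axis, with grey bars for the non-diabetic library, red bars for the diabetic library and 95% exact binomial intervals. Cluster 1, led by Inhba, holds 333 non-diabetic and 2 diabetic cells, and cluster 3, led by Stfa3, 302 diabetic cells and 0 non-diabetic cells.

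The next comparison set the summed expression of the 1618 diabetic monocyte/macrophage cells (27148790 UMIs) against that of the 944 non-diabetic cells (12528169 UMIs), as CPM, UMI counts scaled to a common library total. Acute-phase and antimicrobial genes were among the genes with the highest ratios. Saa3, an acute-phase serum amyloid gene, was at 18078 CPM in the diabetic and 172 CPM in the non-diabetic library, 105-fold higher, a log2 ratio of 6.72 (interval 6.66 to 6.78). S100a8, which encodes a calprotectin subunit, was 20.6-fold higher (19.8 to 21.4), at 4162 against 202 CPM. Lcn2, which encodes an iron-siderophore-binding protein, was 14.1-fold higher (12.9 to 15.5), and Wfdc21 22.8-fold higher (20.4 to 25.5). Cd163 was 28.8-fold higher (24.1 to 35.1), the gap junction gene Gja1 22.0-fold (18.5 to 26.6), the metallothionein gene Mt2 14.2-fold (12.8 to 15.8) and the growth factor gene Ereg 11.2-fold (9.34 to 13.7). Of the 7339 diabetic Cd163 UMIs, 6036 came from the Cd163-led cluster. There Cd163 was at 1717 CPM in 163 diabetic cells and 437 CPM in 8 non-diabetic cells. Stfa3, a stefin protease inhibitor gene, had 9961 diabetic UMIs and 1 non-diabetic UMI, a log2 ratio of 11.58 (9.69 to 17.47). U90926 had 3326 UMIs and 1 UMI, a log2 ratio of 10.00 (8.10 to 15.89). Hebp1 was 23.9-fold higher, a log2 ratio of 4.58 (4.32 to 4.86). Tpm3-rs7 was 32.5-fold higher (26.9 to 40.1), but its transcript is 99.1% identical over 2108 bases to that of Tpm3, which was lower in the diabetic library, so its value is uncertain. Without the Stfa3-led cluster the log2 ratios were 7.27 for Stfa3, 5.91 for Saa3, 3.68 for Wfdc21, 2.85 for U90926, 2.61 for Mt2, 2.46 for Gja1, 1.52 for S100a8, 1.30 for Ereg and 0.60 for Lcn2. Saa3 lies on mm10 chromosome 7 from 46711998 to 46715700 and S100a8 on chromosome 3 from 90668978 to 90670035.

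The genes with the lowest ratios included many that interferon induces. Slfn4 was 13.3-fold lower in the diabetic library (interval 11.7 to 15.1), at 10.1 against 134 CPM. Isg15, a ubiquitin-like interferon-induced gene on chromosome 4 from 156199424 to 156200818, was 7.48-fold lower (7.02 to 7.99), and the chemokine gene Cxcl10 7.33-fold lower (6.95 to 7.74). Oasl2 was 5.21-fold lower, Ifi203 5.17-fold, the interferon regulatory factor gene Irf7 4.81-fold, Mndal 4.24-fold and Ifi211 3.99-fold. Ifi203, Mndal and Ifi211 share stretches of over 95% identity with one another or with related genes, and their single values are uncertain. Slfn4, Isg15, Odc1 and Slc38a1 also have a related gene or gene model at over 95% identity over at least 200 bases, and are uncertain to that extent. Outside this group, the chemokine gene Ccl24 was 8.87-fold lower (8.18 to 9.63), Odc1, which encodes the polyamine enzyme ornithine decarboxylase, 6.10-fold (5.62 to 6.64), Inhba, which encodes an activin subunit, 5.37-fold (5.11 to 5.65, but higher without the cluster it leads, at a log2 ratio of 1.24), and the amino acid transporter gene Slc38a1 4.40-fold (4.12 to 4.71). Of 1600 genes at 100 CPM or more in a library, 71 were at least 2 times higher and 88 at least 2 times lower in the diabetic library. The median log2 ratio of all 11711 measured genes was 0.12.

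**Figure D2:**
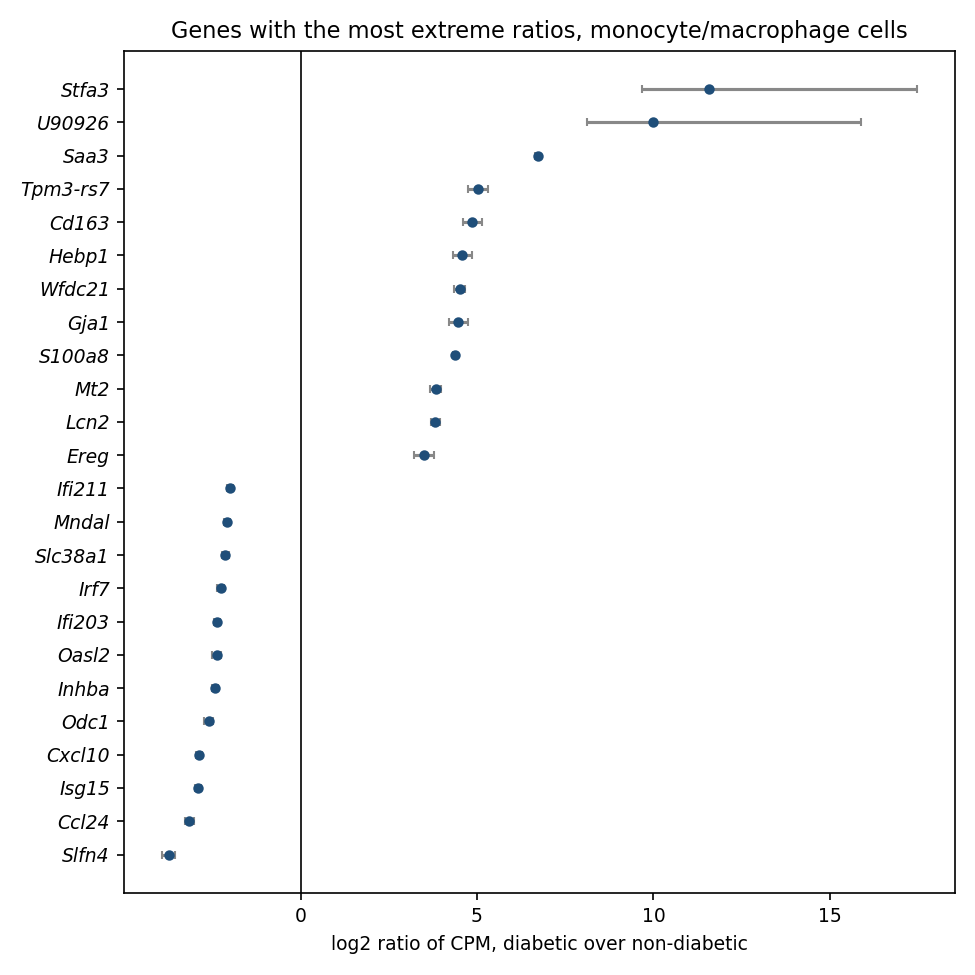
Log2 ratio of CPM, diabetic over non-diabetic, in the summed monocyte/macrophage cells for the 12 genes with the highest and the 12 with the lowest ratio by the fixed rule, with 95% counting intervals. Ratios run from 11.58 for Stfa3 to -3.73 for Slfn4, and the intervals of Stfa3 and U90926 are wide because each had 1 non-diabetic UMI.

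Gene lists fixed in advance summarised these differences. Of 19 measured interferon response genes, 18 were at least 1.5 times lower in the diabetic library and 0 were as much higher. The list median was -2.20 (log2, interval -2.30 to -2.02), at percentile 0 of 10000 random lists matched on expression. Oasl1 was 16.9-fold lower. Of 10 classical monocyte genes, 7 were at least 1.5 times lower and 1 as much higher, with a median of -0.96 (-1.004 to -0.928, percentile 0). Chil3 was 3.86-fold, Plac8 3.11-fold, Ly6c2 2.13-fold and the chemokine receptor gene Ccr2 1.79-fold lower. Of 12 macrophage genes, 9 were at least 1.5 times higher and 0 as much lower, with a median of 1.25 (1.22 to 1.30, percentile 100). The complement genes C1qa, C1qb and C1qc were 3.48-fold, 3.20-fold and 3.32-fold higher, Adgre1, which encodes F4/80, 2.28-fold and the mannose receptor gene Mrc1 2.26-fold. The 2 lists and the clusters' names share their genes, so they are not independent of the class shares.

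Of 19 inflammatory mediator genes, 10 were at least 1.5 times lower and 3 as much higher, with a median of -0.63 (-0.67 to -0.55, percentile 0). The median was -1.32 without the Stfa3-led cluster and -0.29 with all deposited barcodes, and it turned to 0.14 without the Inhba-led cluster. Leaving out either cluster removes cells almost wholly from 1 library, so it cannot show what the lower summed median rests on. Monocyte-like cells, none of them in the Inhba-led cluster, also had a lower median, at -0.76 (-0.85 to -0.67). Macrophage-like cells had -0.12 (-0.25 to 0.15) and an unnamed cluster led by Rab7b 0.40 (0.18 to 0.50). In the summed cells Il23a was 17.4-fold lower, Osm 3.20-fold and Tnf 2.79-fold (interval 2.71 to 2.87), while Il1b stood at 4951 against 6172 CPM. Without the Inhba-led cluster the log2 ratios were -1.72 for Il23a, -1.37 for Osm, -0.87 for Tnf and 0.28 for Il1b. Saa3 and Nos2 were higher, Nos2 3.35-fold, but without the Stfa3-led cluster Nos2 had a log2 ratio of -0.48. Of 20 wound repair and alternative activation genes, 9 were at least 1.5 times lower and 5 as much higher (median -0.48, percentile 0.01), and the median was -0.12 without the Inhba-led cluster. Folr2 was 3.98-fold higher. Arg1 was 1.46-fold lower, but higher without the Inhba-led cluster, at a log2 ratio of 1.74. Of 12 antigen presentation genes, 6 were at least 1.5 times higher and 1 as much lower (median 0.64, percentile 100). H2-Aa was 3.18-fold higher, H2-DMb2 9.36-fold higher and Cd80 2.57-fold lower, and the median was -0.53 when dendritic and other cells were kept in. Of 18 matrix remodelling genes, 8 were at least 1.5 times higher and 6 as much lower (median 0.22, percentile 96.5). The protease genes Mmp9, Mmp12 and Mmp8 were 49.3-fold, 3.68-fold and 3.61-fold higher, and without the Stfa3-led cluster their log2 ratios were 4.91, 0.60 and -0.12.

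Of 15 chemokine receptor and adhesion genes, 15 were lower, 7 of them by at least 1.5 times (median -0.51, percentile 0.02). Immediate early and dissociation genes had a median of -0.48 (percentile 0.12) and cell death and stress genes a median of -0.54 (percentile 0.05). These 2 lists can reflect the handling of the tissue as well as the wound, and they moved in the same direction as the inflammatory list. Metabolic lists differed less. Medians were -0.18 for glycolysis (percentile 4.97), 0.20 for oxidative phosphorylation (96.7), 0.23 for lipid handling (95.2) and -0.09 for hypoxia (12.8). Without the Inhba-led cluster they were 0.12, -0.02, 0.23 and 0.52. Fabp5, which encodes a fatty acid-binding protein, was 5.47-fold higher and Vegfa 2.39-fold lower. Colony-stimulating factor signalling genes had a median of 0.26 (percentile 97.7) and the 4 measured sex-linked genes a median of 0.13 (percentile 57.5).

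**Figure D3:**
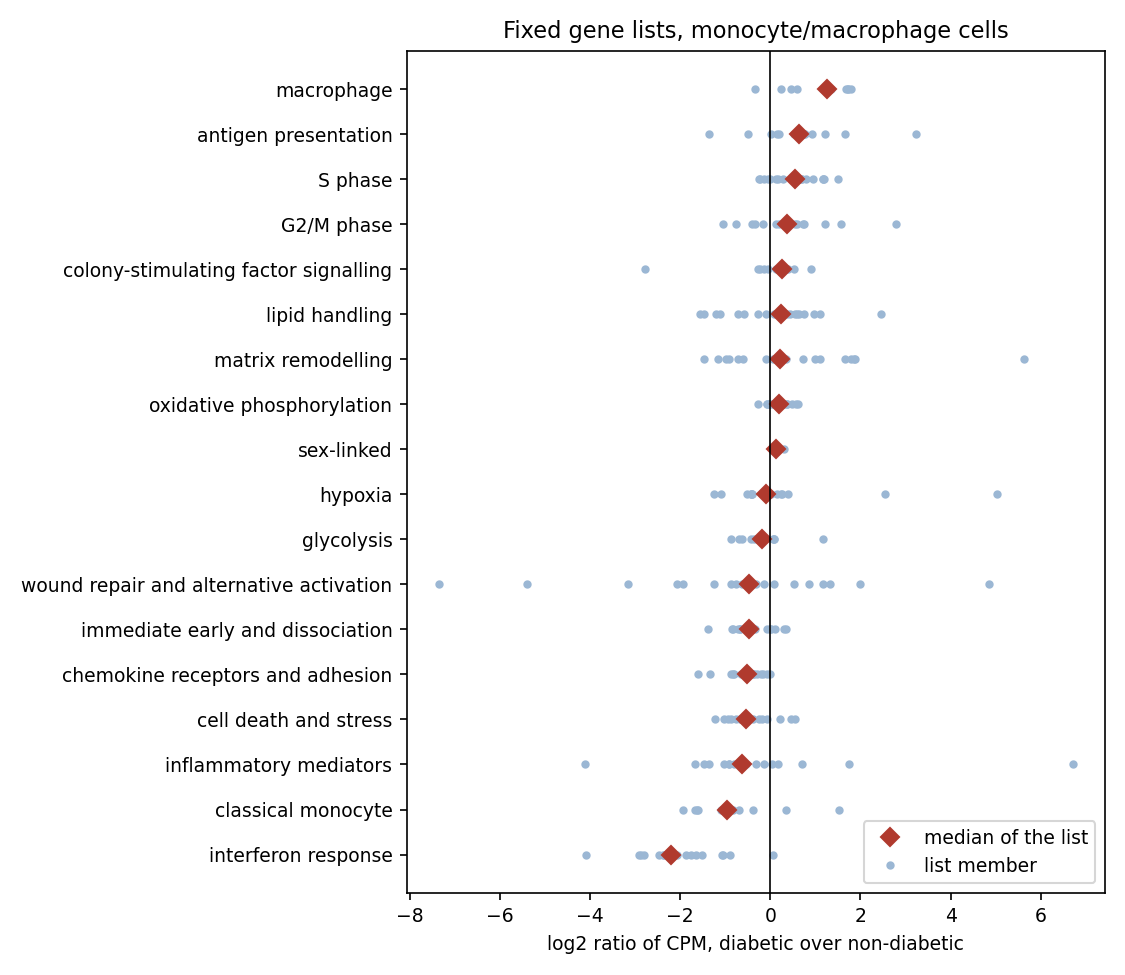
Log2 ratio of CPM, diabetic over non-diabetic, for the measured members (blue points) and the median (red diamonds) of each of the 18 fixed gene lists in the summed monocyte/macrophage cells. Medians run from -2.20 for the interferon response list to 1.25 for the macrophage list.

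The labels' theme of heterogeneity also raises whether these differences were seen within classes. Within monocyte-like cells (329 non-diabetic, 172 diabetic), the inflammatory mediator median was -0.76 (interval -0.85 to -0.67) and the interferon median -0.51 (-0.70 to -0.36). The immediate early and dissociation list (-0.55, -0.64 to -0.49) and the cell death and stress list (-0.54, -0.62 to -0.43), which can reflect handling, were lower in the same cells. Tnf was 4.26-fold, Arg1 4.39-fold, Cxcl1 4.24-fold, Pf4 4.37-fold and Lpl 4.71-fold lower in the diabetic library. Tpm3-rs7, Hebp1, Aig1, S100a8 and Id2 were the 5 highest, with Aig1 5.01-fold, S100a8 4.92-fold and Id2 4.50-fold higher. Most non-diabetic monocyte-like cells came from the Ifit2-led cluster and most diabetic ones from the other monocyte-like cluster. Within that other cluster the interferon median was -0.06 (-0.22 to 0.29) and within the Ifit2-led cluster 0.50 (0.16 to 0.53), so neither showed the lower class median. Interferon-induced genes lead 1 of these clusters, so the split itself narrows interferon differences within each. These 2 medians therefore cannot show whether the class difference is only a mix of clusters. The Arg1 log2 ratio was 0.66 (-0.06 to 1.40) in the other cluster and -1.41 (-1.71 to -1.13) in the Ifit2-led cluster. The inflammatory mediator median was lower in both, at -0.27 (-0.50 to -0.17) and -0.65 (-0.74 to -0.43). Of the unnamed clusters with at least 30 cells of each library, the one led by Rab7b had an inflammatory mediator median of 0.40 (0.18 to 0.50) and an interferon median of -1.40 (-1.71 to -1.21), and the one led by Ccl24 had -0.26 (-0.48 to -0.16) and -1.92 (-2.23 to -1.41). Within macrophage-like cells the interferon median was -1.04 (-1.51 to -0.45), from 22 non-diabetic and 219 diabetic cells, and the inflammatory mediator median -0.12 (-0.25 to 0.15). The classical monocyte list, lower in the summed monocyte/macrophage cells, had medians of 0.20 (0.15 to 0.24) within monocyte-like and 1.33 (0.43 to 1.78) within macrophage-like cells, and the macrophage list, higher there, -0.04 (-0.19 to 0.10) and -0.19 (-0.34 to 0.04). Within macrophage-like cells Saa3 was 27.9-fold, the haptoglobin gene Hp 35.9-fold and Wfdc21 15.7-fold higher, and the scavenger receptor gene Marco, with 0 non-diabetic UMIs, at least 9.85-fold higher. Retnla, with 0 diabetic UMIs, was at least 448-fold lower, Gdf15 130-fold, Cd81 17.0-fold and Ctla2a 11.5-fold lower. Lyve1 was 30.6-fold lower but had a log2 ratio of 1.11 at a stricter cell filter, so its direction is uncertain. The Cd163-led cluster held most diabetic macrophage-like cells and the Ccl8-led cluster most non-diabetic ones.

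The last comparison concerned proliferation. After thinning each cell to 2000 UMIs, 2.18% of the non-diabetic monocyte/macrophage cells (20 of 916, interval 1.34% to 3.35%) and 2.19% of the diabetic cells (35 of 1599, 1.53% to 3.03%) had at least 2 UMIs of the G2/M list, and 28 and 19 shallower cells were left out. Without thinning the shares were 29.4% and 35.5%. Among cells with a UMI of Ly6c2, the gene of the monocyte marker Ly6C, 6 of 213 non-diabetic (2.82%, 1.04% to 6.03%) and 1 of 201 diabetic cells (0.498%, 0.0126% to 2.74%) were cycling by this rule. Among cells without one, 14 of 703 (1.99%, 1.09% to 3.32%) and 34 of 1398 (2.43%, 1.69% to 3.38%) were. The intervals overlapped. The result varied with the random draw: over 20 other thinning draws the shares averaged 2.79% of all non-diabetic and 2.05% of all diabetic cells, and 3.10% and 1.96% of those with a Ly6c2 UMI. For cells without one they averaged 2.69% and 2.06%, and were lower in the diabetic library in 17 of the 20 draws, against the direction given above. In 18 of the 20 draws the share of all cells was lower in the diabetic library, and the 2.18% given first lies near the lower end of their non-diabetic range, 2.07% to 3.49%. A Ly6c2 UMI was found in 23.3% of the thinned non-diabetic and 12.6% of the thinned diabetic cells, against 3.36% and 1.75% of dendritic cell-like cells. The latter were taken as a background, but their own expression of Ly6c2 was not excluded. All were thinned to the same depth. These cycling shares leave out the cluster mixed with stromal cells, with 9 non-diabetic and 53 diabetic cells. Its leading genes include Ube2c and Birc5 of the G2/M list. Only 6 of its 53 diabetic cells had at least 5 UMIs of the fibroblast and endothelial markers. Among all kept cells, the cycling shares after thinning were 3.60% of non-diabetic (39 of 1083) and 2.49% of diabetic cells (43 of 1725). That set also holds dendritic cell-like, neutrophil-like and low-depth cells, and it was thinned in a separate random draw. In summed expression Mki67 was at 23.0 CPM in the diabetic and 13.8 CPM in the non-diabetic library, and Top2a at 4.49 and 2.95 CPM. This direction was not seen within the monocyte-like or macrophage-like class. The log2 ratio of Mki67 was -1.67 (-2.85 to -0.75) in monocyte-like and -0.73 (-1.45 to 0.19) in macrophage-like cells. That of Top2a was -0.57 (-2.47 to 0.88) and -1.40 (-2.95 to 1.18). Of the 15 non-diabetic Mki67 UMIs in macrophage-like cells, 14 came from 2 cells. Outside the summed set, dendritic cell-like cells had 0.30 (-0.36 to 0.93) for Mki67 and 3.36 (2.30 to 4.74) for Top2a. In the summed monocyte/macrophage cells the G2/M median was 0.38 (0.02 to 0.73, percentile 80.1) and the S phase median 0.54 (0.31 to 0.75, percentile 98.4). The G2/M median turned negative with all deposited barcodes. Within monocyte-like cells the 2 medians were -0.43 (-1.12 to 0.20) and 0.06 (-0.30 to 0.35). Within macrophage-like cells they were 0.42 (-0.08 to 1.34) and 0.25 (-0.30 to 1.20).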

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

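The opposite directions below were found after the values were seen, and the difference between the classes was not tested. Arg1, which encodes arginase-1, had a log2 ratio of -2.14 within monocyte-like cells (interval -2.39 to -1.89) and 1.84 within macrophage-like cells (1.65 to 2.04). Mrc1 had 0.26 (0.05 to 0.47) and -0.43 (-0.60 to -0.25). The glycolysis median was -0.21 (-0.28 to -0.16) and 0.50 (0.33 to 0.64), and the hypoxia median -0.26 (-0.52 to -0.15) and 0.47 (0.16 to 0.86). Monocyte-like cells of the 2 libraries sit mostly in different clusters, and the direction given for Arg1 and these lists was not seen in the cluster that holds most of the diabetic ones. There Arg1 had 0.66 (-0.06 to 1.40), glycolysis 0.11 (-0.05 to 0.16) and hypoxia 0.27 (0.05 to 0.44), against -1.41, -0.35 and -0.25 in the Ifit2-led cluster. Mrc1 was higher in both, at 0.56 and 1.06, above its class value. Macrophage-like cells also sit mostly in different clusters. In the Cd163-led cluster, with 8 non-diabetic and 163 diabetic cells, Arg1 stood at 1957 CPM in the non-diabetic and 3483 CPM in the diabetic library and Mrc1 at 1128 and 647 CPM, and in the Ccl8-led cluster, with 14 and 56 cells, Arg1 at 253 and 516 CPM and Mrc1 at 970 and 1079 CPM. The class values therefore reflect the mix of clusters in part. The macrophage-like values rest on 22 non-diabetic cells, and the hypoxia median there was -0.26 with all deposited barcodes and -0.091 at the stricter cell filter.

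A signal also appeared in a cluster that the comparisons leave out because of its level of stromal markers. Only 6 of its 53 diabetic and 4 of its 9 non-diabetic cells had at least 5 UMIs of the fibroblast and endothelial markers. A further 36 diabetic and 4 non-diabetic cells met neither that rule nor the Ctsk rule below. Of these, 35 and 4 had a Csf1r UMI, so most of the cluster's diabetic cells were not stromal by this rule. Its 53 diabetic cells held Ctsk, the cathepsin gene of bone-resorbing osteoclasts, at 2142 CPM (interval 2077 to 2209), and its 9 non-diabetic cells held it at 959 CPM. Few cells carried these levels: 16 of the 53 and 3 of the 9 had a Ctsk UMI. The cluster was led by Ctsk, Slc9b2, Ube2c, Atp6v0d2 and Birc5. Of the 53 diabetic cells, 11 had at least 10 Ctsk UMIs and under 5 UMIs of the stromal markers, with a median of 59132 UMIs, and 11 of these had a Csf1r UMI, 11 an Acp5 UMI and 11 an Atp6v0d2 UMI. Of the 9 non-diabetic cells, 1 met that rule. Outside the cluster, 3 non-diabetic and 6 diabetic cells had at least 10 Ctsk UMIs. The UMI count per cell is far above the library's median, and doublets were not excluded for these cells.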

How the results depend on the processing

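With 1 library per group, neither the variation between mice nor a replicate could be examined. No paired analysis was possible because each group has 1 library. Counting intervals are narrow beside the effect of the processing, so many values left them while keeping their direction. The cause of each shift was not tested. Of 570 alternative values for named genes, 301 stayed within the interval, 263 left it in the same direction and 6 changed sign. Nos2 (-0.48) and Mmp8 (-0.12) did so without the Stfa3-led cluster, Inhba (1.24), Il1b (0.28) and Arg1 (1.74) without the Inhba-led cluster, and Lyve1 within macrophage-like cells (1.11) at the stricter cell filter of 1000 genes and 5% mitochondrial UMIs. The median log2 ratio of all genes shifted by -0.08 with TMM and by -0.08 with DESeq2 scaling.

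Differences in shares are diabetic minus non-diabetic, in percentage points. The share outside the monocyte/macrophage set, -8.17, became 11.2 with all deposited barcodes, -0.861 with genes centred within library and -3.76 when clustered without the interferon list. The monocyte-like share, -24.2, became -16.6 with all deposited barcodes, -27.7 with doublets kept, -14.7 at resolution 2 and -20.1 with centring. The cycling share, 0.00546, became -1.86 with all barcodes, -2.21 at 4000 UMIs, -1.91 with at least 1 UMI and 6.03 without thinning. In cells with a Ly6c2 UMI, -2.32 became 1.05 with doublets kept, -6.04 with at least 1 UMI and 1.72 with the S phase list. In cells without one, 0.441 became -1.64 with all barcodes, -1.50 with doublets kept, -2.40 at 4000 UMIs, -1.48 with at least 1 UMI and 10.6 without thinning. Over 20 other thinning draws, an alternative added after seeing the data, the cycling difference averaged -0.741 and ran from -1.68 to 0.257, with 18 of the 20 below 0, so the random draw alone can move it across 0. By draw, the difference ran from -3.22 to 2.37 with a Ly6c2 UMI and from -1.55 to 0.465 without one. Thinned alternatives that change the cells or the depth also change the draw, so their shifts cannot be separated from it.

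List medians are log2 ratios. With all deposited barcodes the classical monocyte median was -0.76, macrophage 1.58, inflammatory mediators -0.29, G2/M -0.10, antigen presentation -0.36, hypoxia 0.066 and hypoxia within macrophage-like cells -0.26. At the stricter filter macrophage was 1.41, inflammatory mediators -0.54 and hypoxia within macrophage-like cells -0.091. With all filtered cells macrophage was 1.37, inflammatory mediators -0.49, antigen presentation -0.53 and interferon -1.98. The classical monocyte, macrophage and inflammatory medians were -1.04, 1.18 and -0.71 with TMM scaling, -1.05, 1.17 and -0.71 with DESeq2's, and -0.76, 1.20 and -0.69 as means over cells. Alternatives added after seeing the data gave -1.03, 1.19 and -0.70 with the mixed cluster, and -0.68, 1.41 and -1.32 without the Stfa3-led cluster, where interferon was -1.98. Without the Ifit2-led cluster, classical monocyte was -0.70, inflammatory mediators -0.83 and interferon -1.85. Without the Inhba-led cluster, also chosen after seeing the data, classical monocyte was -1.25, macrophage 1.06, interferon -2.31, inflammatory mediators 0.14, glycolysis 0.12, oxidative phosphorylation -0.018 and hypoxia 0.52, and the last 4 changed sign. Within monocyte-like cells, interferon was -0.79 with doublets kept and -0.74 as a mean over cells, and inflammatory mediators -1.29 with all barcodes, -0.88 at the stricter filter and -1.02 with doublets kept. The interferon, classical monocyte and macrophage medians kept their direction in each alternative run.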

Other observations

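Saa3 varied widely between clusters of the diabetic library. It stood at 46800 CPM in the Stfa3-led cluster, 45145 CPM in the Cd163-led macrophage-like cluster and 9856 CPM in the Ifitm1-led cluster. Neutrophil-like cells had 13620 CPM and dendritic cell-like cells 74.3 CPM. S100a8 was at 17377 CPM in the Stfa3-led cluster. Genes not named by the rule, chosen here after their values were seen, also stood apart: over the 5 clusters with at least 30 cells of each library, Gm10260 had 0 to 3 non-diabetic and 292 to 2737 diabetic UMIs per cluster, and the log2 ratio of Gm8797 ran from 2.90 to 4.41 and of Glo1 from 1.71 to 2.03. Near-identical copies were not sought for these genes, so reads shared with a copy were not excluded. A strain difference was not excluded either.

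All tests in the paragraphs that follow were chosen after the result was seen. The interferon list had a median of -2.20. Without the Ifit2-led cluster it was -1.85, and at the stricter cell filter -2.19, which argues against that cluster, or damaged cells, as the whole cause. Free RNA stays open, because the list's members stood at a median of 49.4% (28.8% to 52.6%) of their overall non-diabetic level in the non-diabetic cells of the monocyte-like cluster that is not led by interferon-induced genes, close to the 50% set as the bound. The diabetic state, a strain difference, the mice and the library cannot be told apart with 1 library per group.

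Saa3, Lcn2 and S100a8 were higher in the diabetic library. Neutrophil RNA is argued against by S100a9, at 4.54 UMIs per 100 S100a8 UMIs in diabetic monocyte/macrophage cells and 148 in neutrophil-like cells, and by Retnlg, at 2.69 and 3888 CPM. Free Saa3 RNA is argued against by its level in dendritic cell-like cells, 0.411% of that in monocyte/macrophage cells. The 17 diabetic neutrophil-like cells, however, held Saa3 at 13620 CPM, against 18078 CPM in monocyte/macrophage cells. Their Lcn2 level was 1637 CPM, against 567 CPM. Whether these few cells express the genes or hold free RNA was not tested, so only the dendritic cell-like value speaks against free RNA. Without the Stfa3-led cluster the median of the 3 genes was 1.52, the value of S100a8, with Saa3 at 5.91 and Lcn2 at 0.60. The 3 genes thus stayed higher outside that cluster, Lcn2 by the least. The cluster held 270810 of the 490802 diabetic Saa3 UMIs, 100554 of the 112985 diabetic S100a8 UMIs and 14083 of the 15383 diabetic Lcn2 UMIs. All its cells are diabetic, so leaving it out removes cells of 1 library only. A diabetic effect remains a hypothesis that was not tested against other differences between the libraries.

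Tpm3-rs7 and Hebp1 differed in every shared cluster. The summed level of Tpm3-rs7 and its near-identical copy Tpm3 was 555 CPM in the diabetic and 506 CPM in the non-diabetic library, a log2 ratio of 0.13 (0.09 to 0.18), so reads assigned to a different copy may account for the Tpm3-rs7 difference. Hebp1 ratios ran from 3.04 to 4.92 over the 5 shared clusters, which argues against cells of 1 state as the cause. A strain variant and a diabetic effect on all cells predict the same values for Hebp1 and cannot be told apart here, since the labels speak of strains and give 1 library of each.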
